A study of Caenorhabditis elegans with 2 samples.

How the data were processed

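The samples were 2 biological replicates, per the labels, of an anti-GFP ChIP-seq experiment on whole starved L1 larvae expressing PAX-3 with a GFP tag. Chromatin was sonicated to fragments of 200 to 800 bp, per the labels. Both replicates form 1 group. The deposited files were peak lists in the narrowPeak layout on build ce11, per the accompanying notes of the authors: 1 IDR-thresholded list of 2139 peaks derived from both replicates, 1 pooled relaxed list and 1 relaxed list per replicate, of 30000 peaks each. The aligner, the peak caller, the control and the IDR threshold are not given in the sources used here. The peak signal is the authors' deposited value and was used only to rank and describe peaks within a list. The other deposited value used is −log10 of a q-value per peak, which was read for description and not tested. The IDR list equals the 2139 peaks of highest signal in the pooled list in position and signal. It is thus a cut of the pooled data by signal, and a peak on it need not have been found in each replicate. No row of position and signal was the same in both replicates' lists.

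Peaks were read with Python 3.11.15, pandas 2.3.3 and numpy 2.4.6, and tests were run with scipy 1.17.1 and statsmodels 0.14.6. Figures were drawn with matplotlib 3.10.9. Genes came from Ensembl release 115 for WBcel235, the assembly also called ce11, and bases from the RefSeq copy of that assembly. The 6 nuclear chromosomes (100.3 Mb) and their 19973 protein-coding genes were used. A peak stood for its summit position. Positions are counted from 1.

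A peak was called shared when summits lay within 100 bp. Rotation tests moved all summits of a chromosome by 1 random offset, 1000 times, with a fixed seed. A promoter window ran from 1000 bp upstream to 200 bp downstream of the annotated gene start. Gene lists and name families (at least 15 members) were tested by two-sided Fisher's exact tests against all other protein-coding genes, with Benjamini-Hochberg adjustment over the 30 lists or 117 families. Of the names on the lists, 7 were not found in the annotation. The 25 motifs were searched on both strands of windows centred on the summits. Control windows were drawn from 27439 pooled relaxed summits over 500 bp from any IDR summit, to the same number per GC class (10 classes). Mean GC was 42.9% in peaks, 39.5% in the candidates and 42.8% in the drawn controls. The threshold was an adjusted p of 0.05. Wilson intervals at 95% and limits for a count of 0 (3 counts of the total) cover counting error only. Genes and peaks are not independent replicates, so p-values over them do not measure variation between larvae. Sequencing depth is unknown, since the lists hold no read counts, and gives no further precision.

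Gene lists, motifs, the main tests and most alternatives were fixed before the data were examined. Not among the fixed tests were those of stronger against weaker peaks, of annotation classes other than promoter windows, of chromosomes other than X and of the regions around pax-3 and unc-119, nor the alternatives and tests that the closing section names as chosen afterwards. The text names pax-3 and unc-119, the genes of the 20 IDR peaks of highest signal, up to 4 genes with a promoter peak per list and up to 3 per called family, each by highest signal, and says where a named peak was not matched in both replicates. The peak inside unc-119, those near pax-3, hsp-90 at the second peak and noncoding RNA genes near the strongest peaks were named after their values were seen. The tests were first run on simulated data. For the gene lists, on 19973 genes, 20 of 20 lists with a 5-fold planted excess and 0 of 180 lists without one were called. The simulated lists held 60 genes each, bound independently, while real genes can share a summit and tested lists held as few as 10 genes. These runs therefore do not give the power for small lists or the error rate with shared summits. For the motifs, on 2139 windows, GTCACG planted in 106 windows was called and no motif was called with nothing planted. Both sides of that run came from 1 pool split at random, so it does not cover the different promoter shares of real peaks and controls. For the promoter share, on 2139 summits, 1 of 50 random sets had a rotation p under 0.05, and the excess was found in 50 of 50 sets with 10% of summits placed at gene starts.

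Alternatives changed the peaks used (higher-signal peaks, each replicate alone, without peaks near pax-3 and unc-119 or near short noncoding RNA genes), the distance or overlap for sharing, the promoter window, the background genes, the assignment to genes, the test, the motif window and the control sequence. Where a replicate was left out, the 2139 highest peaks of the other replicate's list were used.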

Results

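Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was used to map where PAX-3, a paired box transcription factor, bound the genome of Caenorhabditis elegans larvae. The protein carried a green fluorescent protein (GFP) tag and was precipitated with an antibody against GFP from whole larvae of the first stage (L1) that had been starved after bleaching, at an age of 6 h. The transgenic strain carries a mutation in unc-119, whose wild-type copy is the usual marker for such transgenes. There was 1 group of 2 biological replicates and no second condition, so the comparisons set the replicates against each other and the peaks against the genome, gene lists and sequence motifs. The deposited lists held 2139 peaks on the list that the authors thresholded by irreproducible discovery rate (IDR), and 30000 relaxed peaks for each replicate and for the pooled data. The 2139 IDR peaks are those of highest signal in the pooled data, so not each of them was found in both replicates. Read counts were not used here and sequencing depth is unknown. All coordinates are in build ce11 and each peak's signal is the authors' own value.

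The first comparison asked how far the replicates marked the same sites. Of the 2139 replicate 1 peaks of highest signal, 1440 (67.3%, 95% Wilson interval 65.3 to 69.3) had a summit within 100 bp of one of the 2139 highest replicate 2 peaks. Random rotation of the replicate 2 summits along each chromosome gave a mean of 0.441% and at most 1.08% (one-sided permutation p = 0.001, the smallest that 1000 rotations can give). The shared part was larger among stronger peaks, at 83% of the top 100, 84.4% of the top 250, 77.1% of the top 1000 and 68.7% of the top 2000. All 20 of the strongest IDR peaks, among them those at rpl-3, tasp-1, nhl-2, cdc-48.1 and cox-5A, were matched in both replicates. In all, 1455 IDR peaks (68.02%) were matched in both top lists, 304 in that of replicate 1 only, 313 in that of replicate 2 only and 67 in neither. Among named peaks, those at ceh-79, a homeobox gene, and wrt-7, a hedgehog-related gene, were matched in neither. The peaks at elt-2, jun-1 and lin-36 were matched in replicate 1 only, and those at cpr-1, hil-7, atf-4 and clec-265 in replicate 2 only. Across the 2016 IDR peaks with a summit in both full replicate lists, Spearman's rho of the signals was 0.73, a value across peaks, which are not independent replicates.

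The second comparison asked where in the gene annotation the sites lay. Promoter windows, from 1000 bp upstream to 200 bp downstream of a protein-coding gene's start, held 1072 of the 2139 summits (50.1%, 95% Wilson interval 48.0 to 52.2). The mean over rotations was 21.5%, so the windows held 2.33 times as many (one-sided permutation p = 0.001, the smallest possible). Coding exons held 56 summits (2.62%) against 20.2% under rotation, and introns and other genic sequence 427 (19.96%) against 30.6% (both lower, permutation p = 0.001). Untranslated regions held 42 summits (1.96%) against 2.93% (lower, permutation p = 0.004). Intergenic sequence held 542 summits (25.34%) against 24.7%, which was not separable from rotation (permutation p = 0.29). A summit in a promoter window was counted in no other class, so the promoter excess by itself lowers the other shares against rotation. The lower intron and untranslated shares therefore need not be a shortage of their own, and an intergenic excess may be hidden. Shares among the summits outside promoter windows were not tested. Among the 1069 peaks of higher signal 59.0% lay in promoter windows, against 41.2% of the other 1070 (odds ratio 2.05, Fisher's exact test, adjusted p = 8.9e-16). Intergenic summits made up 19.6% of the stronger peaks and 31.0% of the weaker ones (adjusted exact p = 4e-09). The larger promoter share of the stronger peaks lowers their other classes in the same way. In total 1397 of 19973 protein-coding genes (6.99%) had a promoter peak, and 355 promoter summits lay in the windows of 2 or more genes, so that the gene served by such a summit is open.

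**Figure D1:**
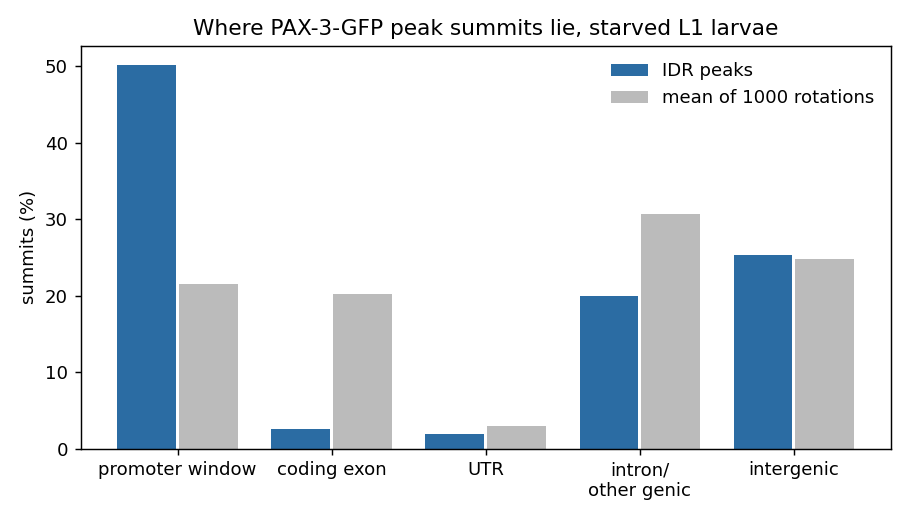
Share of IDR peak summits (blue) in each annotation class, in percent on the vertical axis, beside the mean share over 1000 rotations of the same summits (grey). Promoter windows hold 50.1% of summits against 21.5% under rotation, and coding exons 2.62% against 20.2%.

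Of the 20 peaks of highest signal, 16 lay in promoter windows, 1 in an intron and 3 in intergenic sequence, and 4 of them lay at ribosomal protein genes. The strongest (signal 2034) spanned chromosome V 14055070 to 14055405 and was intergenic, at −2607 bp from the start of F58D12.3. The next (1967, chromosome V 14685610 to 14685933) lay inside hsp-90, which encodes the HSP90 chaperone, and at −276 bp from the start of C47E8.4. Ribosomal protein genes followed, with rpl-3 at 1676 (chromosome III 3867415 to 3867732, at −283 bp from the start), rpl-20 at 1450, rpl-15 at 1222 and rpl-35 at 1201. The rpl-20 summit also lay in the window of Y17G9B.5, and that of rpl-15 in the window of K11H12.8. Shared windows also held the peaks of F25H9.6 and F25H9.7 (1572), tasp-1 and K01G5.10 (1464), nhl-2 and tag-340 (1300), wbp-4 and F56G4.6 (1155), and fib-1, which encodes fibrillarin, and mut-15 (1120). Single promoter windows held those of T07F10.3 (1505), tos-1 (1207), cdc-48.1, an AAA ATPase gene (1158), egg-5 (1151), cept-2 (1092) and the cytochrome c oxidase gene cox-5A (1052). The egg-5 peak lay within 300 bp of sls-2.4, a small nuclear RNA gene, and of R12E2.18, a noncoding RNA gene. Of the remaining peaks, 1 was in an intron of ppfr-1 (1202), 1 was at −4763 bp from the start of the calmodulin gene cmd-1 (1162) and 1 was at −2771 bp from the start of T04C4.3 (1097). The ppfr-1 peak lay within 300 bp of the noncoding RNA genes F16A11.7 and anr-20. The cmd-1 peak lay as near to linc-128, a long intergenic noncoding RNA gene, and that of nhl-2 and tag-340 to the noncoding RNA gene F26F4.14.

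The tagged gene and the transgene marker were examined because extra copies of their sequence can raise local signal. The tests below count peaks and do not measure their height, so they cannot decide whether signal was raised. No IDR summit lay in the promoter window of pax-3 (WBGene00003939, chromosome II 10146570 to 10152865, plus strand). The gene with 50000 bp to each side held 2 IDR peaks against 2.17 at the chromosome's mean density, and 31 pooled relaxed peaks against 30.8 (two-sided exact binomial p = 0.93). These 2 peaks lay at the promoter of daf-19, which encodes an RFX transcription factor (signal 203, matched in replicate 1 only), and at that of arv-1 and R05H5.4 (signal 250). At unc-119 (WBGene00006843, chromosome III 10902641 to 10908935, plus strand) no summit lay in the promoter window, and 1 peak of signal 304 lay inside the gene, 791 bp downstream of its start. The region of the same flanks held 2 IDR peaks against 2.79 at the chromosome's mean density, the other being near oxi-1 (signal 126, matched in replicate 2 only), and 33 pooled relaxed peaks against 32.1 (two-sided exact binomial p = 0.86).

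The third comparison asked how peaks were spread over the chromosomes. Chromosome III held 362 peaks (16.9%) where its share of promoter windows predicts 12.9%, a ratio of 1.31 (two-sided exact binomial test, adjusted p = 7.3e-07). Chromosomes II (312 peaks, ratio 0.851) and V (473 peaks, ratio 0.886) held fewer than predicted (adjusted exact p = 0.0042 for each). Chromosome I (319 peaks, ratio 1.05, adjusted exact p = 0.32) and chromosome IV (318 peaks, ratio 0.913, adjusted exact p = 0.095) did not pass the threshold. The X chromosome held 355 peaks (16.6%, 95% Wilson interval 15.1 to 18.2) against 14.5% predicted, a ratio of 1.14 (exact binomial p = 0.00685, adjusted p = 0.0103). Of the X peaks 35.2% lay in promoter windows, against 58.3% on chromosome I. The X ratio was 1.00 without replicate 1 (exact binomial p = 0.951) and 0.939 against the X share of chromosome length (p = 0.202), so it rested on the replicate and the expectation used. The call also ended among the higher-signal peaks (1.04, exact binomial p = 0.60), without peaks near short noncoding RNA genes (1.09, p = 0.11) and with peaks matched in both replicates (1.09, p = 0.18). Against chromosome length the excess on III held (13.7% predicted, exact binomial p = 3.3e-05). The deficit on II did not (15.2%, exact binomial p = 0.417), V turned to a share above the 20.9% predicted (exact binomial p = 0.159) and IV fell below the 17.4% predicted (exact binomial p = 0.00156).

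The fourth comparison asked which kinds of genes had promoter peaks, using 30 lists chosen before the data were examined. Genes of protein synthesis, protein folding and mitochondrial energy production stood out. The series holds no ChIP of another factor, so sites that many ChIP experiments share cannot be told from sites of PAX-3 here. Ribosomal protein genes had a promoter peak in 50 of 82 cases (61.0%, odds ratio 21.5, Fisher's exact test, adjusted p = 1.5e-35). Oxidative phosphorylation genes followed with 15 of 47 (31.9%, odds ratio 6.29, adjusted exact p = 2.9e-06), heat shock and chaperone genes with 19 of 62 (30.6%, odds ratio 5.94, adjusted exact p = 2.3e-07) and translation factors with 15 of 63 (23.8%, odds ratio 4.19, adjusted exact p = 1.3e-04). Chemoreceptor genes went the other way, with 17 of 1309 (1.299%, odds ratio 0.165, adjusted exact p = 3.5e-22). These 5 lists were called under each alternative that was run, but the sizes moved. With each peak given to the nearest start the odds ratios fell to 5.42 for ribosomal proteins, 3.17 for oxidative phosphorylation, 2.49 for heat shock and 2.44 for translation factors (largest adjusted exact p = 0.031). Against genes with a relaxed summit those of ribosomal proteins and translation factors were 12.9 and 2.57, and among the higher-signal peaks that of chemoreceptors was 0.0615.

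**Figure D2:**
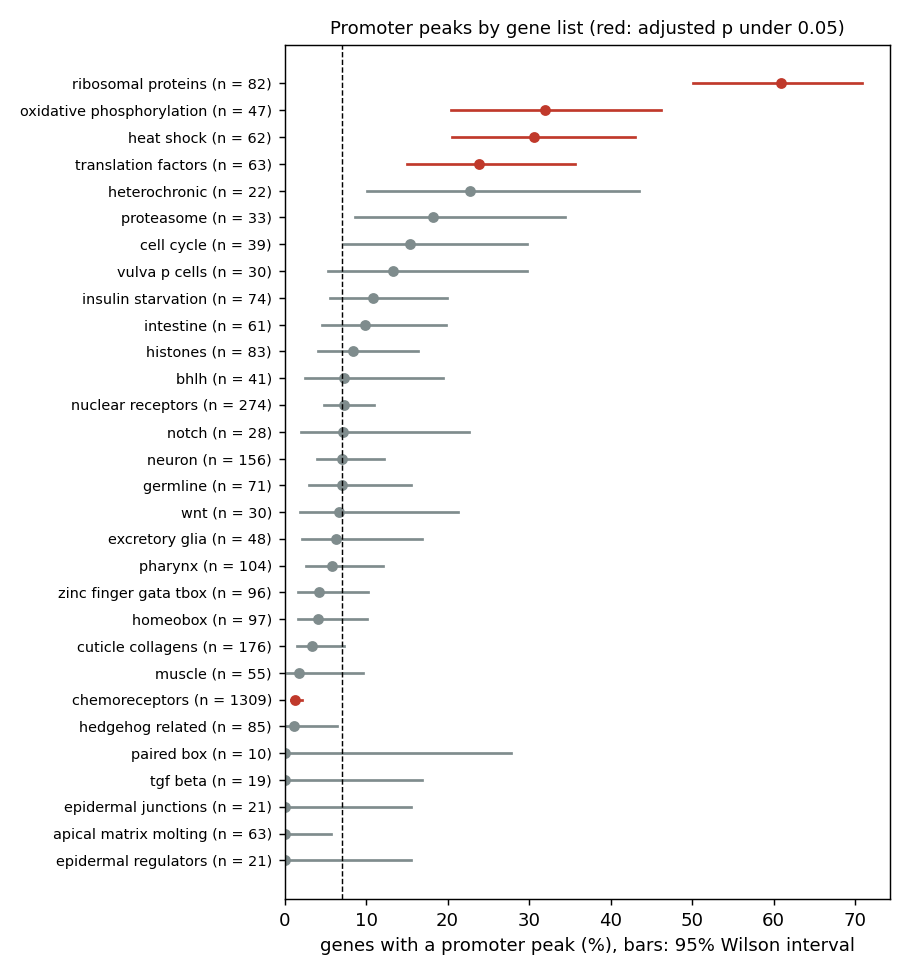
Share of the genes of each of the 30 lists with a promoter peak, in percent on the horizontal axis, with 95% Wilson intervals as bars and the number of genes in brackets. The dashed line is the share of all protein-coding genes (6.99%), and red marks the 5 lists with an adjusted p under 0.05, with ribosomal proteins at 61.0% and chemoreceptors at 1.299%.

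Within the ribosomal protein list, small-subunit genes such as rps-19 (signal 881), rps-1 (715) and rps-28 (654) joined the large-subunit genes named above. Translation factor peaks were strongest at iff-2 (854), eif-3.B (668), eef-1A.2, an elongation factor 1 alpha gene (620), and eif-3.C (606). After cox-5A, the oxidative phosphorylation peaks of highest signal lay at the ATP synthase gene atp-1 (615), cox-5B (521) and cox-6A (359). Chaperone gene peaks lay at hsp-1, an HSP70 gene (1000.1), the mitochondrial chaperonin gene hsp-60 (988), the cytosolic chaperonin subunit cct-8 (794) and hsp-3, a BiP-type gene (637). The chemoreceptor genes with the strongest peaks were srh-16 (486), sri-5 (362), srz-62 (229) and srx-48 (224).

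Lists of epidermal genes, included because the epidermis is a tissue in which PAX-3 is known to act, held few promoter peaks and did not pass the threshold in the main test. The counts were 0 of 21 for epidermal regulators and 0 of 21 for epidermal junction genes, which allow shares of up to 14.3% each. For apical matrix and molting genes the count was 0 of 63, which allows up to 4.76% (adjusted exact p = 0.094), and for hedgehog-related genes 1 of 85, wrt-7 (signal 136, adjusted exact p = 0.10). Hedgehog-related genes were called lower without replicate 2 (0 genes, adjusted exact p = 0.0157) and by logistic regression with upstream distance, which also called apical matrix and molting genes lower. Cuticle collagens had a promoter peak in 3.41% of genes (6 genes), led by col-38 (338), col-71 (323), col-148 (209) and col-63 (183). Homeobox genes had 4 of 97, which were ceh-38 (387), ceh-23 (270), dsc-1 (247) and ceh-79 (118). Paired box genes had 0 of 10 and TGF-beta pathway genes 0 of 19, which allow up to 30% and 15.8%. With the nearest start the TGF-beta list turned direction and was called higher (odds ratio 4.77, adjusted exact p = 0.018). The list of GATA, T-box, Sox, Fox and other developmental transcription factors was called higher there too (odds ratio 2.07, adjusted exact p = 0.031).

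Among regulators of development, the heterochronic genes, which set the timing of larval fates, had 5 of 22 (22.7%, odds ratio 3.92, adjusted exact p = 0.080). The strongest were nhl-2 (1300), puf-9 (866), ain-1 (334) and lin-46 (291). This list missed the threshold in the main test and passed it in 5 alternatives, which were without replicate 2 (adjusted exact p = 0.0113), among the higher-signal peaks, with peaks matched in both replicates, with the nearest start and by logistic regression with upstream distance. It was further from the threshold with the window of 500 bp upstream (odds ratio 1.75, adjusted exact p = 0.67) and against genes with a relaxed summit (3.04, 0.26). Cell cycle genes had 6 of 39 (adjusted exact p = 0.16), with lin-35, the retinoblastoma homologue (891), pcn-1, which encodes PCNA (738), efl-1, an E2F gene (403), and cdc-6 (216). Vulva and P cell genes had 4 of 30 (adjusted exact p = 0.39), namely lin-35, lin-53 (528), lin-7 (211) and lin-36 (124). Wnt genes had 2 of 30, mig-5 (486) and wrm-1 (392.5), and Notch genes 2 of 28, sel-10 (297) and adm-4 (199).

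Markers of the other tissues in a whole larva did not pass the threshold in the main test. With each peak given to the nearest start at any distance, neuronal genes (odds ratio 2.18, adjusted exact p = 0.0054), insulin and starvation genes (3.10, 0.0015) and nuclear receptors (1.78, 0.0085) were called higher. Among the higher-signal peaks their odds ratios turned to 0.418, 0.293 and 0.559, and that of neuronal genes was 0.342 without replicate 1 and 1.27 without replicate 2, with no call in these settings. Neuronal genes had 11 of 156, led by unc-76 (416), ida-1 (266), egl-21 (201.1) and unc-36 (162). The pharyngeal list had 6 genes (5.77%), led by pqn-51 (481), pqn-59 (442), pqn-39 (292) and pqn-71 (214). All those named belong to the pqn name family (6 of 56), and their expression in the pharynx was not examined here. Intestinal genes had 6 of 61, led by cpr-3 (420) with cpr-1 (148), elt-2, the intestinal GATA factor (139), and clec-63 (136). Germline genes had 5 of 71, led by mex-1 (690), cgh-1 (273), xnd-1 (154) and nos-3 (143). Muscle genes had 1 of 55, cpn-3 (504), and excretory and glial genes 3 of 48, which were the proton pump genes vha-13 (378), vha-12 (253) and vha-8 (209). Insulin and starvation genes had 8 of 74, led by ins-39 (467), ins-14 (175), nhr-49 (154) and gpd-2 (142).

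Proteasome genes had 6 of 33 (18.2%, adjusted exact p = 0.094), led by pas-1 (517), rpn-3 (438), rpn-11 (298) and pbs-1 (205). Without replicate 2 the odds ratio rose from 2.96 to 5.25 and the list was called (adjusted exact p = 0.0012), as it was with peaks matched in both replicates (0.036) and with the window of 2000 bp upstream (0.049). Histone genes had 7 of 83, with his-37 (910) and the H2A.Z gene htz-1 (618) ahead of his-72 (168) and hil-7 (143). Nuclear receptors had 20 of 274, led by nhr-47 (427), nhr-196 (305), nhr-291 (275) and nhr-142 (263). Genes of bHLH factors had 3 of 41, mdl-1 (230), hlh-11 (188) and the hypoxia factor hif-1 (163). The list of GATA, T-box, Sox, Fox and other developmental transcription factors had 4 of 96, zip-4 (289), jun-1 (172), elt-2 and atf-4 (132). Of these, zip-4, jun-1 and atf-4 fall among the other factors.

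Name families, tested without a prior choice of function, gave 12 of 117 past the threshold. Higher were rpl (29 of 47), rps (20 of 31), sec (7 of 19), lin (11 of 47), hsp (7 of 22), dnj (8 of 29), cyn (5 of 16) and vps (7 of 31). The sec genes, most of protein secretion, were led by sec-61.G (933), sec-61.B (488) and sec-15 (292). The dnj genes encode J-domain co-chaperones and were led by dnj-13 (589), dnj-19 (427, a summit shared with nhr-47) and dnj-9 (391.8). The cyn genes encode cyclophilins and were led by cyn-10 (548), cyn-3 (495) and cyn-1 (366). Genes named lin were led by lin-35, lin-54 (837) and lin-9 (561). The vps family, with vps-51 (891, a summit shared with lin-35), vps-32.1 (454) and vps-60 (405), had the weakest call (adjusted exact p = 0.047). The calls of sec, hsp, dnj, cyn and vps ended when each peak was given to the nearest start, and that of lin ended against genes with a relaxed summit (odds ratio 3.14, adjusted exact p = 0.056). The vps and cyn calls ended in 5 and 3 alternatives in all. Lower were the chemoreceptor families str (1 of 193, str-163 at 158), srh (2 of 220, srh-16 and srh-269 at 150.9) and srw (0 of 109). The lectin-domain family clec was lower too (5 of 240, odds ratio 0.28), led by clec-78 (223), clec-186 (167) and clec-265 (148). The clec call ended with peaks matched in both replicates (adjusted exact p = 0.0504) and with the window of 500 bp upstream (0.18), and the srw call among the higher-signal peaks (0.11) and with that window (0.053).

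The fifth comparison asked whether sites of paired box proteins and other factors were more frequent in the peaks than in control windows of the same GC content. The short paired-domain core GTCACG was present in 152 of 2139 peak windows (7.11%) and in 4.02% of control windows (odds ratio 1.83, Fisher's exact test, adjusted p = 1.2e-04). Its longer form GTCACGC was in 1.59% against 0.842% (odds ratio 1.90, adjusted exact p = 0.068), and passed the threshold in 14 of 20 other draws of control windows, chosen after seeing the data. It was also called without replicate 2 (2.72, adjusted exact p = 0.0069), without peaks near pax-3 and unc-119 (3.12), without peaks near short noncoding RNA genes (2.45) and against windows 500 bp to either side (3.44), and not without replicate 1 (1.54) or against dinucleotide shuffles (1.31). Each changed peak set had its own draw of control windows. Over the 20 draws with all peaks the odds ratio of GTCACGC ranged from 1.49 to 3.44, so these changes are not separated from the draw. The extended paired-domain site CGTCACGSTT, with S for C or G, was in 1 peak window and 1 control window and passed in 0 of the 20 other draws. The homeodomain site TAATTA was in 6.08% against 4.25% (odds ratio 1.46, adjusted exact p = 0.029), and fell to an odds ratio of 0.817 against windows 500 bp to either side. Without replicate 1 its call was lost too (odds ratio 1.33, adjusted exact p = 0.10). Its paired forms, palindromes spaced by 2 and by 3 bases, did not pass the threshold (adjusted exact p = 0.75 and 0.13). The palindrome spaced by 2 bases was called with peaks matched in both replicates, where no control window held it and no finite odds ratio exists. Both permuted cores were slightly less frequent in peaks (odds ratios 0.888 and 0.760) and not past the threshold.

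Sites of several other factors were also more frequent in peaks. The control windows were matched for GC and not for place. Of the 27439 candidates 6205 lay in promoter windows, against 1072 of the 2139 peaks, so sequence common to promoters can add to these differences. Among summits in promoter windows GTCACG was in 7.09% of IDR peaks and 3.66% of these relaxed ones, without a match for GC. Outside promoter windows it was in 7.12% of IDR peaks (odds ratio inside against outside 0.995), so promoter placement did not raise the GTCACG share among IDR peaks. The other factors' sites were not compared within promoter windows. The largest odds ratio among the 8 motifs called higher was that of the GA repeat GAGAGAGA, in 7.11% of peaks against 2.71% (2.74, adjusted exact p = 5.6e-10). The E-box CACGTG was in 7.81% against 4.58% (odds ratio 1.76), the E2F site in 10.4% against 7.67% (1.39) and the Sp1 site in 2.29% against 1.08% (2.16). Against windows 500 bp to either side, which were not matched for GC, the odds ratios were larger for the GA repeat (6.60), Sp1 (6.25), GTCACG (2.98), CACGTG (2.96) and E2F (2.15), and against shuffles CACGTG had 3.04. The GATA, CAGCTG and CREB sites were called only in alternatives, such as the shuffles (1.89 and 2.26 for the 2 GATA forms, 1.93 and 32.5). Forkhead (1.71) and AP-1 (1.83) sites were also called. In the 20 other draws of control windows the forkhead site passed in 6, AP-1 in 3, Sp1 in 17 and TAATTA in 12, while GTCACG, CACGTG, the GA repeat and the E2F site passed in all 20. The Sp1, forkhead and AP-1 calls ended among the higher-signal peaks, without peaks near short noncoding RNA genes and with peaks matched in both replicates. The forkhead call also ended without replicate 1 (adjusted exact p = 0.062) and without replicate 2 (0.097), and the AP-1 call without replicate 1 (0.12) and without peaks near pax-3 and unc-119 (0.13), and both against shuffles and in narrower and wider windows. The ETS (0.483), nuclear receptor (0.687), Hox and Pbx (0.706) and TEAD (0.751) sites were called lower. In the other draws these passed in 12, 3, 18 and 12 of 20, and the nuclear receptor call ended in 7 alternatives, among them without replicate 2 and with peaks matched in both replicates. The ETS call ended in 6 alternatives, among them the higher-signal peaks and those matched in both replicates, the TEAD call in 4, among them without replicate 2, and the Hox and Pbx call in 2. The E2F site was more frequent among the stronger peaks, 12.7% against 8.04% (adjusted exact p = 0.0096), and GTCACG was not, 6.92% against 7.29%. With a window of 51 bp only the E2F site was called higher, and GTCACG had an odds ratio of 1.68 (adjusted exact p = 0.11). The summit was the midpoint of the interval in 1841 of the 2139 peaks (86.1%), which limits the precision of such narrow windows.

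**Figure D3:**
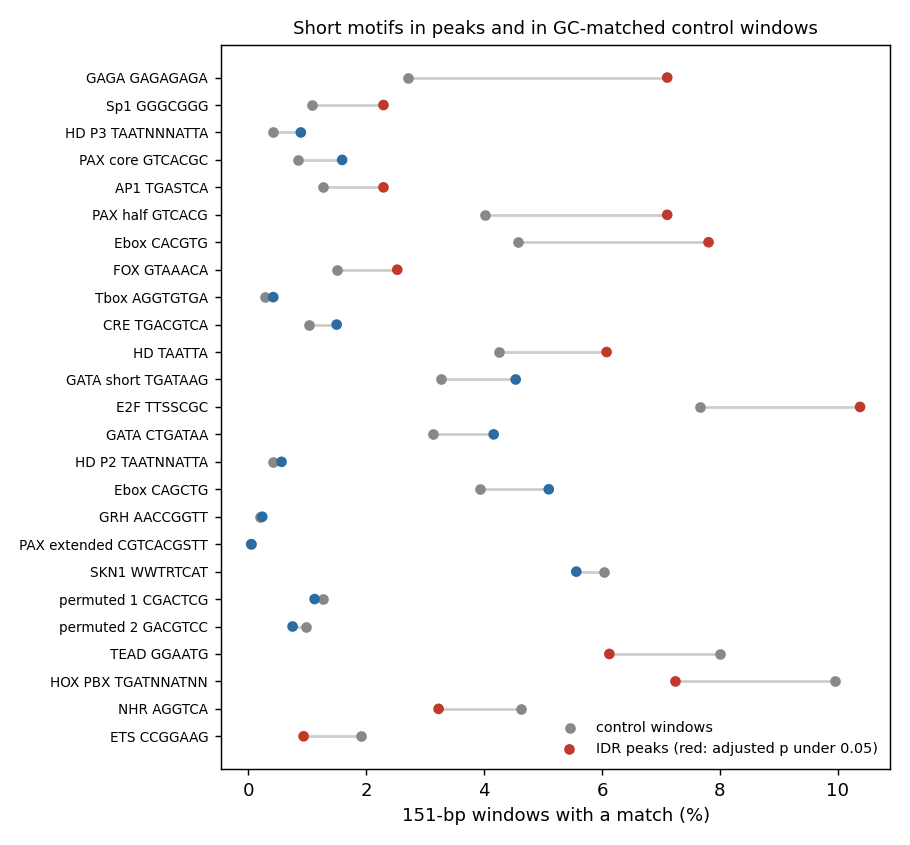
Share of windows with a match to each motif, in percent on the horizontal axis, in IDR peaks (coloured points, red where the adjusted p is under 0.05) and in GC-matched control windows (grey points). GTCACG stands at 7.11% against 4.02% and GAGAGAGA at 7.11% against 2.71%.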

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

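The alternatives that use only peaks matched in both replicates, and other draws of control windows, were chosen after seeing the data. No paired analysis was possible because there is 1 group. The pooled list's highest peaks are the IDR list itself, so that alternative changed nothing by construction. Replicate overlap stayed above rotation in each alternative (57.04% to 77.4%), as did the promoter share (40.3% to 62.1%). Name families called ranged from 9 to 18. Depth is unknown, so what it limits was not tested. The cause was not tested for any change below, except that fewer peaks or shorter windows hold fewer matches. Each peak set and window length tested against GC-matched controls had its own draw of control windows, so its motif changes are not separated from the draw. Leaving out peaks near pax-3 and unc-119 removed only 2 IDR peaks at each gene, so few that the draw can account for the motif changes there.

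The X call ended with a ratio of 1.04 among the higher-signal peaks, 1.09 without peaks near short noncoding RNA genes, 1.09 with peaks matched in both replicates, 0.939 against chromosome length, and the ratio was 1.00 (call ended) to 1.16 without either replicate. The number of gene lists called was 11 with each peak given to the nearest start, 8 by logistic regression with upstream distance and 5 to 8 without either replicate, each time with all 5 main lists. The lists gained with the nearest start were heterochronic, neuron, insulin and starvation, nuclear receptors, TGF-beta, and GATA, T-box and other developmental factors. By logistic regression they were heterochronic, hedgehog-related and apical matrix, and without replicate 2 heterochronic, hedgehog-related and proteasome. The number of motifs called higher was 5 among the higher-signal peaks, 1 with a window of 51 bp and 5 to 9 without either replicate. In 20 draws of control windows 5 to 10 motifs were called higher.

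Of 360 values for lists 37 crossed an odds ratio of 1, 35 of them called neither way, and of 272 values for motifs 33 did, 29 of them called neither way. The motif values leave out alternatives with no finite odds ratio. No value for a called family did so, of 144, and 16 lost their call. Odds ratios that crossed 1 follow. Among the higher-signal peaks they were Wnt 1.53, insulin and starvation 0.293, neuron 0.418, pharynx 1.31, intestine 0.357, germline 0.621, excretory and glial 1.43, histones 0.528, nuclear receptors 0.559, E-box CAGCTG 0.964, SKN-1 1.02 and T-box 0.799. Without peaks near short noncoding RNA genes they were permuted core CGACTCG 1.15 and T-box 0.799. With peaks matched in both replicates they were Wnt 1.23, neuron 0.450, intestine 0.582, excretory and glial 1.15, E-box CAGCTG 0.896 and SKN-1 1.09. With the nearest start they were Wnt 2.58, TGF-beta 4.77 (called), pharynx 1.10, germline 0.615, histones 0.803, GATA, T-box and other developmental factors 2.07 (called) and paired box 1.15. By logistic regression they were Wnt 1.09 and germline 0.966. With the window of 2000 bp upstream they were Wnt 1.48, Notch 0.741 and germline 0.730, and with that of 500 bp insulin and starvation 0.738, neuron 0.698, germline 0.506 and bHLH 0.897. Against genes with a relaxed summit they were neuron 0.685, intestine 0.797 and nuclear receptors 0.857.

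With a motif window of 51 bp they were GTCACGC 0.900, TAATTA 0.873 (call lost), permuted core GACGTCC 1.25 and SKN-1 1.63, and with the widest window the palindrome spaced by 3 bases 0.970, CGACTCG 1.26, CAGCTG 0.975, Grainyhead 0.666 and T-box 0.944. Against windows 500 bp to either side they were TAATTA 0.817 (call lost), the palindromes spaced by 2 and 3 bases 0.598 and 0.883, CGACTCG 1.79, GACGTCC 1.39 and Grainyhead 0.909. Against dinucleotide shuffles they were AP-1 0.872 and ETS 1.18 (calls lost), Grainyhead 0.624 and T-box 0.527. Without peaks near pax-3 and unc-119 they were CGACTCG 1.202, SKN-1 1.02, Grainyhead 0.833 and T-box 0.691. Without either replicate the ranges were neuron 0.342 to 1.27, intestine 0.977 to 1.43, germline 0.991 to 1.05, excretory and glial 0.928 to 1.19, nuclear receptors 0.918 to 1.10, CGACTCG 0.958 to 1.05, SKN-1 1.00 to 1.07 and T-box 0.888 to 2.00.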

Other observations

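The tests on noncoding genes, 7-mers and Rb and E2F genes below, and those on upstream space, transcribed genes, promoters near tRNA genes, dinucleotide shuffles and summit position, were chosen after the results were seen. Short noncoding RNA genes lay near many peaks. Summits within 300 bp of tRNA genes numbered 75 against a rotation mean of 7.90 (9.50-fold), of snoRNA genes 64 against 5.21 (12.3-fold) and of snRNA genes 22 against 1.90 (11.6-fold), each with a two-sided permutation p of 0.002, the smallest possible. The 75 summits lay near 79 of 612 tRNA genes, which were 43 of the 276 on X and 36 of the 336 on autosomes. Of the 75 summits 40 lay on X. Those near snRNA genes were mostly strong, with 18 among the higher-signal peaks and 4 among the others (Fisher's exact test, adjusted p = 0.022). The excess was not particular to these classes. Summits near other ncRNA genes (333, 3.42-fold), antisense RNA genes (10, 2.99-fold), miRNA genes (9, 2.71-fold) and lincRNA genes (18, 2.39-fold) exceeded rotation too (largest two-sided permutation p = 0.016). Pseudogenes (24 against 95.4) and piRNA genes (31 against 74.5) were rarer than under rotation (permutation p = 0.002 for each).

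Of 8192 7-mers, 430 were more frequent in peaks than in control windows after adjustment and 337 less. GAGACGC was in 219 peaks (10.2%) against 2.95% of controls (odds ratio 3.76, Fisher's exact test, adjusted p = 2.3e-19), within the longer GAGACGCAGA in 138 peaks against 31 controls. It was in 12.63% of the stronger and 7.85% of the weaker peaks (Fisher's exact test, p = 2.7e-04). Its share was 10.2% inside promoter windows and 10.3% outside. Of 9 genes of Rb and E2F complexes picked after the lin family was seen, 6 had promoter peaks (lin-35, lin-54, lin-9, lin-53, efl-1 and lin-36), and lin-37, lin-52 and dpl-1 had none.

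Ribosomal protein genes had promoter peaks far more often than other genes. Longer upstream space is argued against, since the odds ratio was 20.1 (95% interval 12.8 to 31.5) with upstream distance in a logistic model. An excess of the paired-domain core GTCACG is argued against too, since it was in 0 of 47 such promoter peaks and 76 of 1025 others (odds ratio 0, upper limit 1.05, Fisher's exact test, p = 0.072). Most of the other promoter peaks lacked this core as well, so the test cannot decide on contact at other sequences. Recovery of heavily transcribed genes in general stays open. Summits near tRNA genes, read by another polymerase, were 9.50-fold over rotation, but this is an unexplained pattern of the same peaks. Of 612 tRNA genes 79 lay near a summit, and transcription was not measured, so this value cannot decide. The design has no second group, so no biological explanation was tested between groups.

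For tRNA genes near peaks, protein-coding promoters are argued against, since 20% of these summits lay in a promoter window (95% interval 12.5 to 30.4). Reads shared between identical copies stay open. A copy elsewhere was found for 84.8% of tRNA genes near a summit and 75.4% of the others (odds ratio 1.82, 95% interval 0.938 to 3.81, Fisher's exact test, p = 0.086), too few genes to decide. No biological explanation was tested.

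For the excess of GTCACG, 3 explanations stay open. Outside the E-box form GTCACGTG the odds ratio was 1.63 (95% interval 1.2 to 2.22), and against dinucleotide shuffles 1.37 (1.06 to 1.78), both with intervals that reach the 1.2 set as the limit. Contact of the paired domain may add to it: 25.21% of matches lay in the central 51 bp of the windows where length predicts 16.9% (exact binomial p = 0.0012), but the centre is richer in GC (46.2% against 38.8%) and 86.1% of summits are interval midpoints. A comparison with 51 other 6-mers of the same bases and 1 CG replaced that test after this was seen, and 58.8% of them had a lower central share than GTCACG. The central share was larger than that of GTCACG for the E2F site (32.1%), the permuted core CGACTCG (31.1%) and the E-box CACGTG (28.7%), among others. For the homeodomain site TAATTA it was 9.49%, below the share that length predicts (adjusted exact binomial p = 0.0014). These data do not separate contact from base composition.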
